A study of Mus musculus with 6 samples.

How the data were processed

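Chromatin immunoprecipitation on promoter arrays (ChIP-chip) was measured in C2C12 cells, a mouse myoblast line that fuses into myotubes in low serum. Per the labels, cells carried a retroviral vector for TEAD4 with a Flag-HA tag or the empty vector, were kept in puromycin, differentiated for 5 days in 2% horse serum, and were fixed for 10 min in 0.4% formaldehyde. Chromatin was precipitated with an anti-Flag antibody. Per the labels' protocols, 4 µg of precipitated (IP) DNA was labelled with Cy5 and 4 µg of input DNA with Cy3, the same way on every array. There were 2 TEAD4 samples, which the labels call duplicates, and 1 control sample. Each was hybridised to a set of 2 Agilent promoter array designs, 6 arrays in all. Nothing in the labels says whether the duplicates came from separate cultures, so the spread between them may be technical. P-values from comparisons of samples rest on that spread, and those from counts of genes or windows measure no spread between samples.

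The intensity values were made by the authors' scanner software, Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited processed intensities are background-subtracted with a fitted spatial surface, detrended, and scaled by 1 linear dye factor per channel and array. The deposited log10 ratios are log10 of IP over input from those processed intensities. The series matrix values deposited by the authors equal these log10 ratios (largest difference 0) and are not centred: their medians lie between -0.182 and 0.00124. Per the file headers, the control arrays were extracted with extended dynamic range and the TEAD4 arrays were not. The genome build of the probe coordinates is not given in the sources used here. Coordinates are printed as the files give them.

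From the processed intensities, log2 of IP over input was computed and centred on each array's median. Control spots, probes without a chromosomal position and probes flagged as non-uniform on any array were left out, which kept 236180 probes on design 1 and 235690 on design 2. A window was a probe with its neighbours within 500 bp on each side, held at least 3 probes, and took their mean. There were 428057 windows, and 16512 genes had at least 1. Genes were those the array annotation gives for a probe. Of 16840 symbols, 16459 were updated by accession, 206 by symbol and 118 by synonym through a RefSeq table of GRCm38.p6, used for names only, and 57 kept the file's name. An array symbol that differs is given in brackets.

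TEAD4 and control were compared with limma 3.58.1 in R 4.3.3 within each design, with a Simes p per gene over its windows and Benjamini-Hochberg adjustment over all genes, at a two-sided threshold of 0.05. This left 1 residual degree of freedom, from the 2 TEAD4 samples. The test therefore leaned on a variance pooled over windows, with 13.3 prior degrees of freedom on design 1 and 13.9 on design 2. The 1 control sample was assumed to vary like the TEAD4 samples. Beside it stood rules of size with no test: a window at least 2-fold above (or below) the control in both TEAD4 samples, and a window at least 2-fold above input in both TEAD4 samples or in the control. The 13 gene lists were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists, and their median top window was placed among 10000 random lists matched on the number of windows. All of these choices, the lists and the rule for named genes were made before the data were examined. The lists tested among genes enriched over input, the genes named for the largest enrichment over input and the demand for enrichment over both input and control were added after seeing the data.

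The rule for named genes took up to 15 genes with the largest TEAD4 minus control, up to 4 passing members of each list, 15 fixed genes, the 3 genes with the largest control enrichment and the 2 with the lowest TEAD4 minus control. Only those that bear on a comparison are printed. The fixed gene Tead4 had 2 probes and no window, so the tagged gene's own promoter was not measured.

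The limma step was tested on simulated data: the TEAD4 duplicates' residuals were shuffled over the probes of 3 arrays, and 193 genes among 16512 were raised over a run of probes. In TEAD4 against control, 46.2% of 65 genes raised 2-fold, 98.4% of 63 raised 4-fold and 98.5% of 65 raised 8-fold were recovered. Of 16289 unaltered genes, 87 were called. With a variance taken to fall with the number of probes, 24 were called. With normal noise in place of the residuals these counts were 46 and 5. Shuffling over probes removes any correlation of neighbouring residuals. The SD pooled over windows was 0.197 and 0.182 on designs 1 and 2 with shuffled residuals, against 0.239 and 0.216 in the data. The prior degrees of freedom were 40.9 and 137.7 against 13.3 and 13.9. Recovery and false calls may therefore look better here than in the data. In a simulation added after seeing the data, the simulated control's shuffled residuals were widened. They were multiplied by the real control's median absolute deviation of log ratios over the mean of the TEAD4 samples'. This treats the wider spread as noise that is independent between neighbouring probes, and it need not match the real control's spread across windows. Then limma called 94.2% of the unaltered genes, 7887 higher and 7458 lower, and the 2-fold rule took 67.4% of them.

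The 3 samples were scanned on 3 days, 1 per sample, with 1 array of each design per day. No fit with day as a block was possible, and batch and group cannot be told apart. The number of arrays limits the precision. Alternatives covered background correction (normexp with offset 50), loess, the series matrix, window widths of 300 bp and 1000 bp, window medians, at least 4 probes, dim probes, scaling, variance models, thresholds of 1.5-fold and 3-fold, and each TEAD4 sample left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.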

Results

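TEAD4 is a DNA-binding transcription factor of the TEAD family, which recruits the co-activators YAP and TAZ. The series asked which promoters tagged TEAD4 occupied in differentiated C2C12 cells. Precipitated DNA was measured against input DNA at promoters in 2 TEAD4 samples and in 1 sample of cells with the empty vector. The median IP spot signal was 3.62 and 4.66 times the local background on design 1 in TEAD4 samples 1 and 2, and 4.73 and 5.45 times on design 2. In the control sample it was 1.84 and 2.06 times. Input signal over background was higher in the control (5.54 and 7.57) than in the TEAD4 samples (at most 3.69).

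The control sample had wider ratios than the TEAD4 samples. Across windows the SD of log2 IP/input was 0.38 and 0.40 in TEAD4 samples 1 and 2, and 1.04 in the control. The median window of the control lay at 0.26, against -0.01 in each TEAD4 sample. Of all windows, 26.4% were at least 2-fold over input in the control.

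**Figure D1:**
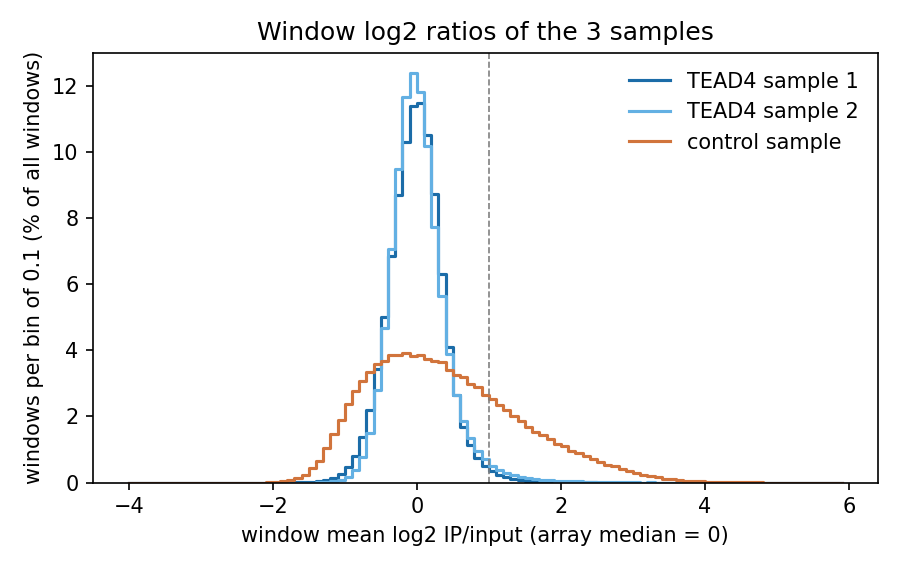
Distribution of window mean log2 IP/input in the 2 TEAD4 samples and the control sample, as percent of all windows per bin of 0.1, with the dashed line at 2-fold enrichment. The control curve is broad (SD 1.04) and extends to the right, while both TEAD4 curves are narrow (SD 0.38 and 0.40).

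Promoters enriched over input in both TEAD4 samples included those of muscle genes and of genes that respond to YAP. A total of 859 genes (5.20%) had such a window, against 54 genes (0.327%) with a window at least 2-fold below input in both. All enriched windows, with or without an annotated gene, formed 861 separate regions. Among the largest mean enrichments was Ankrd2, a stretch-responsive ankyrin repeat protein of muscle, at a log2 IP/input of 2.78 ± 0.24 (SD, n = 2) with -0.53 in the control. Capn2, the large subunit of a calpain protease, was at 2.84 ± 0.26 (SD, n = 2) with -0.74 in the control. Map4k4, a kinase of the Hippo network, was at 2.70 ± 0.02 (SD, n = 2) with -0.15 in the control. Chrng, the gamma subunit of the embryonic acetylcholine receptor, was at 2.57 ± 0.53 (SD, n = 2) with 0.62 in the control.

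The other genes among the 15 with the largest mean were Tlcd2 [2010305C02Rik], Mxra8, S100a11, Trip6, Nutm1 [Nut], Ect2, Dgat2, Arsj, Fam71f1 [BC048651], and Gemin5 and Mrpl22, which share a promoter region. Capn2, Mxra8, S100a11, Ect2, Gemin5, Mrpl22, Nutm1, Dgat2 and Arsj rest on 3 probes. Nutm1, Dgat2 and Arsj had SDs of 1.34, 1.35 and 0.87, and the same windows of the control were at 2.17, 2.85 and 2.90. The limma test of the TEAD4 samples against 0, over all genes, called 3957 higher and 1948 lower. By the 2-fold rule over input, the count was 1330 in sample 1 alone and 2568 in sample 2 alone. With 952 genes in both lists, 207 were expected from independent lists of these lengths. The dye orientation was the same on every array, so a shared dye effect could also raise this overlap.

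Of the YAP-responsive genes, 11 of 36 had a promoter enriched over input in both TEAD4 samples, against 5.15% of other genes (Fisher's exact test, adjusted p = 8.34e-06). This was the highest share among the 13 lists under that rule. Without TEAD4 sample 2 housekeeping genes had a higher share, 39.1% against 30.6%, and excitation-contraction genes the same 30.6%. Thbs1, which encodes the matrix protein thrombospondin 1, was at 2.36 ± 0.05 (SD, n = 2) with -0.55 in the control. Ankrd1, a muscle ankyrin repeat gene, was at 2.11 ± 0.42 (SD, n = 2) with -0.12 in the control, in a window on chromosome 19 from 36184707 to 36185539 at -119 bp from its start. Ccn1 [Cyr61], a secreted matricellular protein, was at 2.11 ± 0.25 (SD, n = 2) with 1.10 in the control, in a window on chromosome 3 from 145588966 to 145589913 at -2076 bp from its start. Ccn2 [Ctgf] was at 1.27 ± 0.30 (SD, n = 2) with 0.56 in the control. Dab2 passed at 1.36 ± 0.23 (SD, n = 2) but was higher in the control, at 1.93. This list was written with knowledge of the field, and so were some members of the muscle and unfolded protein response lists.

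Genes of the contractile apparatus followed, with 11 of 46 sarcomere genes enriched (Fisher's exact test, adjusted p = 7.66e-05). Cryab, a small heat shock protein of the Z-disc, was at 2.33 ± 0.16 (SD, n = 2) with 1.13 in the control. Tnni1, slow troponin I, was at 1.96 ± 1.00 (SD, n = 2) with -0.85, so its samples differed widely. Acta1, skeletal actin, was at 1.40 ± 0.35 (SD, n = 2) with 0.27, and Ttn, the giant spring protein titin, at 1.21 ± 0.19 (SD, n = 2) with -0.70. Mylpf, Myom2, Actc1 and Tnnt2 also passed, at 1.66, 1.85, 1.33 and 1.18, but the control was close behind at 1.14, 1.48, 1.00 and 0.77. So did Myoz2, Tpm3 and Cavin4 [2310039E09Rik], at 1.20, 1.55 and 1.69, with -0.35, 0.51 and -0.62 in the control. The windows of Tpm3 and Actc1 lay far from the annotated starts, at 8562 and -5459 bp. Those of Tpm3, Actc1, Tnni1 and Myom2 rest on 3 probes each. At 3-fold over input 2 sarcomere genes were left (Fisher's exact test, adjusted p = 0.161).

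Of the genes for excitation-contraction coupling, membrane and metabolism, 8 of 36 passed (Fisher's exact test, adjusted p = 0.00139). Besides Chrng they included Chrna1 at 1.48 ± 0.04 (SD, n = 2) and Cav3, muscle caveolin, at 1.15 ± 0.13 (SD, n = 2), with 0.03 and 0.86 in the control. Cacnb1 at 1.19 and Casq1 at 1.17 passed but were higher in the control, at 1.76 and 1.72. Of the fusion and adhesion genes 4 of 20 passed (Fisher's exact test, adjusted p = 0.047). They included Mymk [1110002H13Rik], a membrane protein needed for myoblast fusion, at 2.29 ± 0.32 (SD, n = 2) with -0.32 in the control. Cdh15 was at 1.36 with 0.15 in the control, but Itga7 at 1.22 and Bin1 at 1.10 barely exceeded the control's 1.18 and 1.08. Neither list passed once the same window also had to be 2-fold above the control (Fisher's exact test, adjusted p = 0.207 and 0.238), with normexp background correction (0.293 for each), or at 3-fold (0.395 and 0.355). Without TEAD4 sample 1 the fusion list had an adjusted p of 0.161 by Fisher's exact test.

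Among myogenic regulators 4 of 29 passed (Fisher's exact test, adjusted p = 0.0999). With the same window also 2-fold above the control 2 of 29 did (Fisher's exact test, adjusted p = 0.366). The list's call depended on the setting: by Fisher's exact test the adjusted p was 0.0206 without TEAD4 sample 1 (10 of 29), 0.0372 without sample 2 (6 of 29), 0.00849 with loess and 0.0128 at 1.5-fold, but 0.05003 with normexp and 0.0915 at 3-fold. Myog, the myogenic factor myogenin, was at 2.14 ± 0.35 (SD, n = 2) with 1.02 in the control, in a window on chromosome 1 from 136101187 to 136101681 at -5211 bp from its start, the outermost one measured. Tead1, Vgll4 and Myf6 were the others. The window of Tead1 lay 81099 bp from its annotated start, so it is not at that start's promoter, and that of Myf6 lay at -5259 bp. The window of Vgll4 was higher in the control, at 2.27, than in TEAD4, at 1.65 ± 0.06 (SD, n = 2). The windows of Myog, Myf6 and Vgll4 rest on 3 probes each. Myod1, a relative of Myog, had 1.00 in sample 1 and 2.22 in sample 2 in its top window and did not pass.

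The unfolded protein response list had 5 of 41 members enriched (Fisher's exact test, adjusted p = 0.0999). Without TEAD4 sample 2 it had 12 of 41 (Fisher's exact test, adjusted p = 0.000175) and without sample 1 it had 8 of 41 (0.558). By Fisher's exact test it passed with loess (adjusted p = 0.0399) and at 1.5-fold (0.000444), but not with normexp (0.293) or at 3-fold (0.395). With the same window also 2-fold above the control 1 of 41 passed, 2.44% against 2.56% of other genes. Creb3l2 was at 2.08 ± 0.40 (SD, n = 2) with -0.23 in the control, and Ddit3, a stress-induced transcription factor, at 1.22 ± 0.06 (SD, n = 2) with 0.74. Hspa5, a chaperone of the endoplasmic reticulum, was at 1.57 ± 0.49 (SD, n = 2), below the 2.74 of the control, and Syvn1 at 1.12 was below 2.65. Of the cell cycle genes 4 of 33 passed (Fisher's exact test, adjusted p = 0.13), with Myc at 1.88 ± 0.34 (SD, n = 2) and 1.13 in the control. Ccnd1 at 1.18 and Ccnd2 at 1.27 passed but were higher in the control, at 3.21 and 1.72. Cdkn1a, a cell cycle inhibitor, reached 0.98 ± 0.04 (SD, n = 2) and did not pass.

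Promoters active in most cells and promoters of other tissues gave a background. Of ribosomal protein genes 7 of 84 passed (Fisher's exact test, adjusted p = 0.272), and of housekeeping genes 4 of 23 (Fisher's exact test, adjusted p = 0.0633). These results depended on the setting. Housekeeping genes passed by Fisher's exact test with 9 of 23 without TEAD4 sample 1 (adjusted p = 0.014), with 9 of 23 without sample 2 (0.000175), and at 1.5-fold (0.000288). Ribosomal genes passed it without sample 2, with 16 of 84 (adjusted p = 0.0018), and at 1.5-fold (6.25e-13). Eno1 was at 2.24 ± 0.45 (SD, n = 2) with 0.11 in the control, and Ldha at 1.41 with 1.07. Actb was at 1.23 ± 0.07 (SD, n = 2) with 1.30 in the control, Tpi1 at 1.24 with 2.26, and Gapdh at 0.80 ± 0.52 (SD, n = 2) did not pass. Rpl4, Rpl3, Rps26 and Rpl36 were at 1.35, 1.33, 1.24 and 1.33, with -0.38, 0.05, -0.18 and 0.53 in the control. Rps28 was at 1.13 with 1.03. Rplp0 [Arbp] at 1.90 and Rpl21 at 1.13 passed but were higher in the control, at 4.73 and 1.33. Liver genes gave 0 of 25, neuronal genes 0 of 25 and haematopoietic genes 1 of 28 (Fisher's exact test, adjusted p = 0.692, 0.692 and 1). Without TEAD4 sample 1 their shares were 8.0%, 4.0% and 17.9% in that order, against 15.6%, 15.6% and 15.5% of other genes. Without sample 2 they were 0%, 12.0% and 3.57%, against 8.07%, 8.05% and 8.06%. Alb was at 0.03 ± 0.05 (SD, n = 2). Olfactory receptor genes gave 3 of 825, fewer than other genes (Fisher's exact test, adjusted p = 1.08e-14). The gap was smaller without TEAD4 sample 1, at 9.58% against 15.9% of other genes (odds ratio 0.562 instead of 0.0632). Without sample 2 it was 0.606% against 8.45%. Ckm, muscle creatine kinase, was at 0.37 ± 0.65 (SD, n = 2) in its top window, at -7929 bp from its start, and did not pass.

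**Figure D2:**
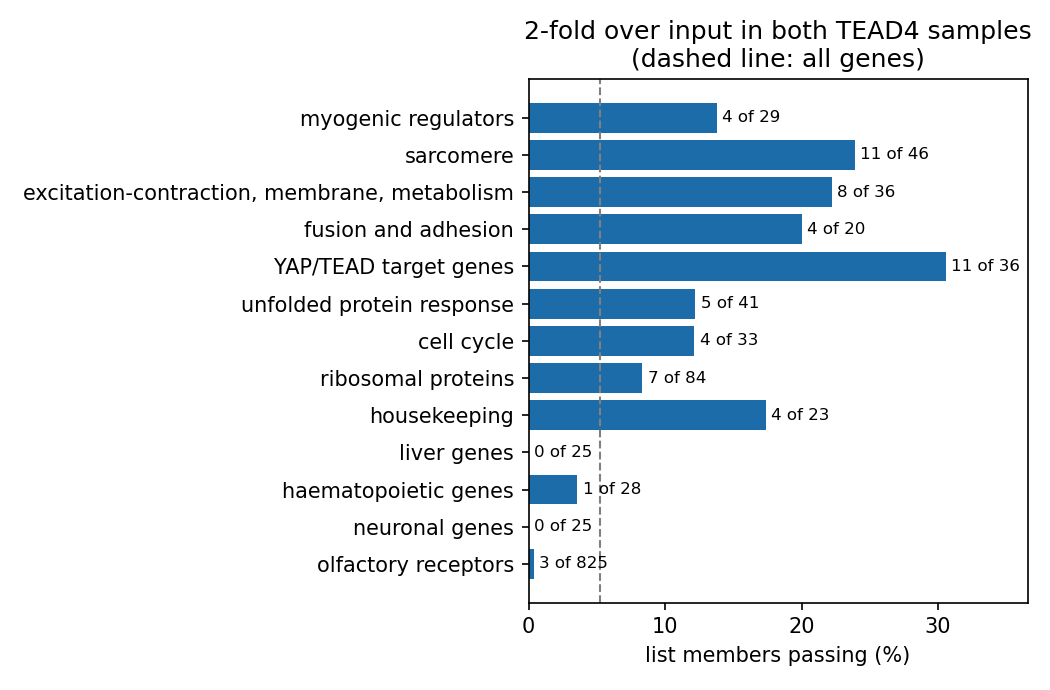
Share of each list's members, in percent, with a window at least 2-fold over input in both TEAD4 samples, with counts beside the bars and all genes (5.20%) as the dashed line. YAP target genes (11 of 36) and sarcomere genes (11 of 46) have the longest bars, and olfactory receptors (3 of 825) lie near 0.

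The YAP-responsive list passed at each threshold, with 22 of 36 at 1.5-fold and 4 of 36 at 3-fold (Fisher's exact test, adjusted p = 4.08e-07 and 0.00218). The threshold changed the calls of other lists. At 1.5-fold over input 57.0% of ribosomal and housekeeping genes passed, against 53.4% of sarcomere, excitation-contraction and YAP-responsive genes together. At 2-fold the shares were 10.3% and 25.4%. By the limma test of TEAD4 against 0, which called 24.0% of all genes higher, ribosomal genes had the highest share of the lists, 65.5% against 61.1% of YAP-responsive genes (Fisher's exact test, adjusted p = 4.99e-15 and 7.14e-06). The sarcomere, excitation-contraction, fusion, housekeeping, unfolded protein response, myogenic and cell cycle lists passed too, with adjusted p from 7.14e-06 to 0.0289 by Fisher's exact test. The counts over all genes and those adjusted over the list alone were 22 and 24 of 36 YAP-responsive genes, 26 and 28 of 46 sarcomere genes, and 55 and 60 of 84 ribosomal genes. For excitation-contraction genes they were 19 and 22, fusion 12 and 13, myogenic 14 and 16, unfolded protein response 20 and 20, cell cycle 14 and 14, and housekeeping 14 and 16. For liver genes they were 3 and 3, haematopoietic 2 and 1, neuronal 2 and 2, and olfactory receptors 31 and 32. The medians of the top windows of the YAP-responsive, sarcomere and excitation-contraction lists each lay above 100% of the random lists matched on the number of windows, and so did those of the ribosomal and housekeeping lists.

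Enrichment over input was far more frequent in the control than in the TEAD4 samples. A total of 14134 genes (85.6%) had a window at least 2-fold over input in the control, including 805 of the 859 genes enriched in TEAD4. With normexp background correction the control count was 3136, while that of both TEAD4 samples was 555. Within the same windows the overlap was smaller: 32.3% of the 2822 windows enriched in both TEAD4 samples were also 2-fold over input in the control. The largest control values were 5.49 at Pcbd2, 5.39 at Galnt1 and 5.29 at Mcl1, where the TEAD4 means were 0.29, 0.20 and 0.16. A window at least 2-fold above both input and control in both TEAD4 samples was present in 422 genes. Among these, YAP-responsive genes gave 8 of 36 and sarcomere genes 7 of 46 (Fisher's exact test, adjusted p = 1.79e-05 and 0.000664).

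**Figure D3:**
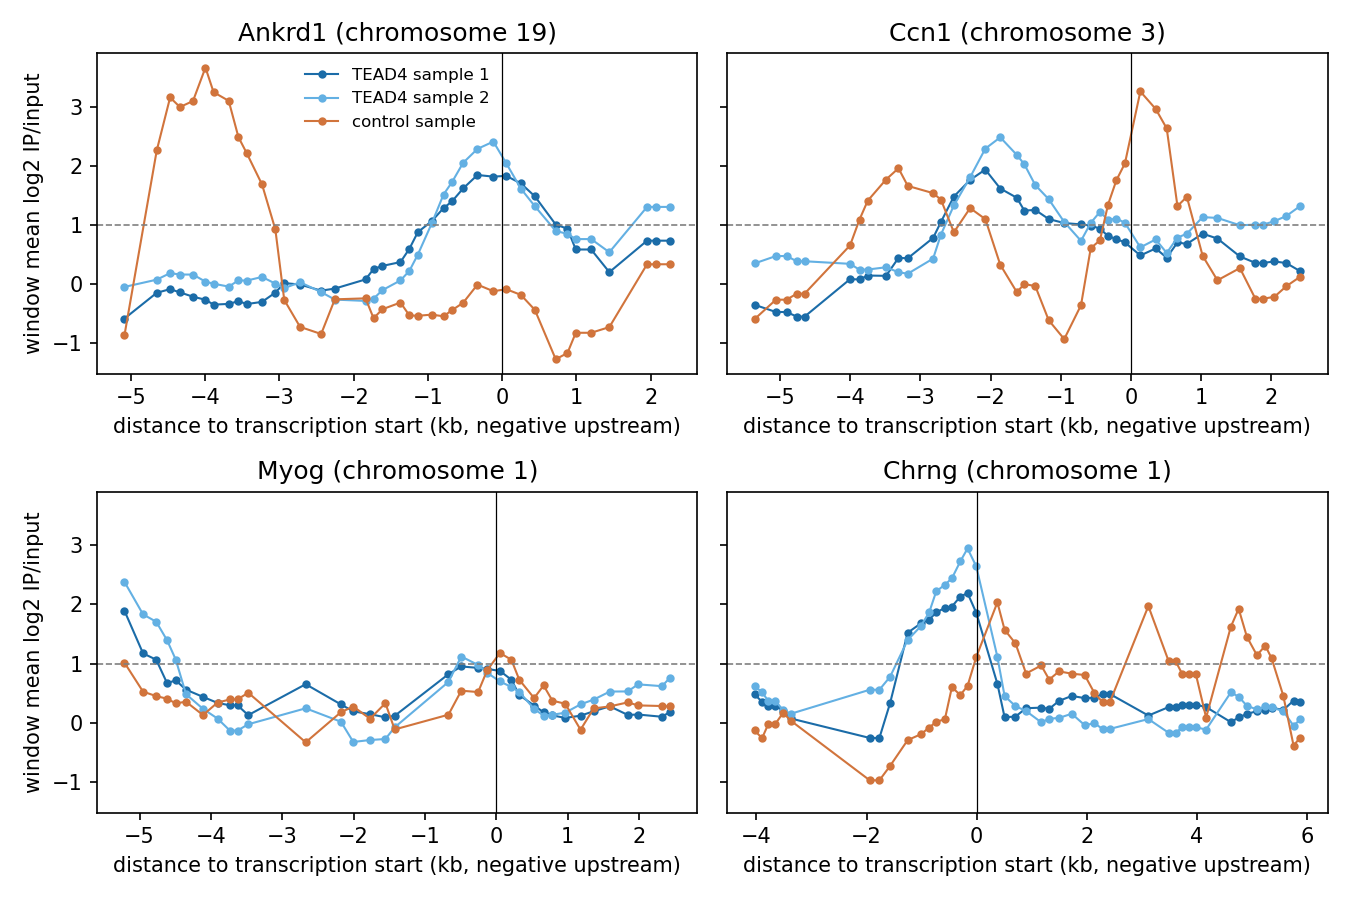
Window mean log2 IP/input by distance to the transcription start (kb) at Ankrd1, Ccn1, Myog and Chrng in the 2 TEAD4 samples and the control, with the dashed line at 2-fold. Both TEAD4 samples were high near the start at Ankrd1 (mean 2.11) and Chrng (mean 2.57), with the control there at -0.12 and 0.62. They were high at Myog (mean 2.14) in the outermost upstream window, beyond which nothing was measured, with the control at 1.02. At Ccn1 (mean 2.11) they were high upstream, with the control at 1.10. In other windows the control peaked where TEAD4 was lower. It reached 3.66 at -3996 bp of Ankrd1 (TEAD4 -0.27 and 0.04) and 3.25 at 134 bp of Ccn1 (TEAD4 0.48 and 0.62). At 375 bp of Chrng it was at 2.03 (TEAD4 0.66 and 1.11).

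Against the control, the windows with the largest excess in TEAD4 belonged to Slc9a9, Capn2, Fam71f1 [BC048651], Ankrd2 and Cxcl5, at TEAD4 minus control differences of 3.81, 3.58, 3.37, 3.31 and 3.22. The next were Zdhhc16, Wdfy1, Bloc1s1, Kctd7, Mxra8, Klf6, Olfr456, Myl12a [2900073G15Rik], Thbs1 and Wasf1, from 3.15 down to 2.96. The order and sizes depended on the setting. With normexp Ankrd2 was the largest of these 15 at 3.24, while Slc9a9 was at 2.26, Cxcl5 at 1.69 and Wasf1 at 0.64. With 1000 bp Slc9a9 was at 1.77 and Ankrd2 at 1.17. Slc9a9 rests on 3 probes with 3.11 and 1.65 in the TEAD4 samples (SD 1.03, n = 2). Capn2, Cxcl5, Zdhhc16, Mxra8, Klf6 (SD 1.07, n = 2) and Olfr456 rest on 3 probes too. In all 15 windows the control was below 0, from -0.24 at Mxra8 to -1.62 at Wasf1, so part of each difference is a low control value. Limma, which takes a gene's direction from its window of lowest p, called 14 of the 15 higher. It called Zdhhc16 lower, from another window at -3.42. Of the 15, Wasf1 alone was not 2-fold over input in both TEAD4 samples. A window at least 2-fold above the control in both TEAD4 samples was present in 4937 genes, and one at least 2-fold below it in 13514 genes. Without TEAD4 sample 1 the first count was 7588. The lowest differences were -5.42 at Armcx2 and -5.20 at Pcbd2.

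By limma 2040 genes were higher and 13374 lower in TEAD4 than in the control, a higher share of 13.2%. With the arrays scaled to a common median absolute deviation, the limma split turned to 128 genes higher and 34 lower. The SD that limma pools over windows rose with this scaling, from 0.239 to 0.405 on design 1. The split of the few calls left therefore does not show that scale sets the direction. By the size rule the same scaling gave 2897 above and 7458 below, a higher share of 28.0% against 26.8% unscaled, so that split did not turn. With quantile normalization the counts were 1181 and 1276, with normexp 328 and 802, and with windows centred on their own median 4333 and 11246. The size rule with normexp gave 1318 above and 1788 below, and centred windows 8539 and 12082. The median window difference was -0.26, so directions are relative to that shift. In simulated data in which the control had its observed spread, limma called 94.2% of unaltered genes and the 2-fold rule took 67.4%, so single calls against this control cannot be told from its spread.

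Of the lists, YAP-responsive genes passed the size rule against the control most often, with 22 of 36 members against 29.8% of other genes (Fisher's exact test, adjusted p = 0.00189). The list's median top window difference of 1.24 lay above 99.9% of the matched random lists, that of the ribosomal list above 99.7% and that of the olfactory receptor list above 100%. With loess 0 lists passed. No other list passed (fusion and adhesion 11 of 20, sarcomere 20 of 46, unfolded protein response 19 of 41, ribosomal proteins 36 of 84, excitation-contraction 14 of 36, myogenic regulators 10 of 29, cell cycle 12 of 33, housekeeping 9 of 23, neuronal 10 of 25, liver 8 of 25, haematopoietic 7 of 28, olfactory receptors 254 of 825). By limma against the control, olfactory receptors alone passed, with 237 of 825 higher (Fisher's exact test, adjusted p = 2.5e-37), but 427 were lower. By the size rule 50.8% of them lay below the control, against 83.5% of other genes, and 30.8% above it, against 29.9%. Their median window was -0.36 and -0.19 in the TEAD4 samples and -0.41 in the control. Of the YAP-responsive genes limma called 9 higher and 26 lower, and adjusted over the list alone the counts were again 9 and 26. Of the sarcomere genes it called 12 higher and 30 lower, again the same counts adjusted over the list alone. Over the list alone 224 olfactory receptors were higher, and no other list changed its count.

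Windows enriched over input in both TEAD4 samples lay within 500 bp of a transcription start more often than other windows, at 28.2% against 17.7% (Fisher's exact test, odds ratio 1.82, p = 4.46e-41). Neighbouring windows share probes, so this p is too small. Windows 2-fold above the control lay there less often, at 5.93% against 18.2%, and windows 2-fold below it more often, at 37.0% against 12.5% (Fisher's exact test, odds ratios 0.283 and 4.12, p too small to be represented). The control itself had its highest median, 1.32, from 0 to 500 bp downstream of the start, where the TEAD4 medians were 0.22 and 0.17.

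**Figure D4:**
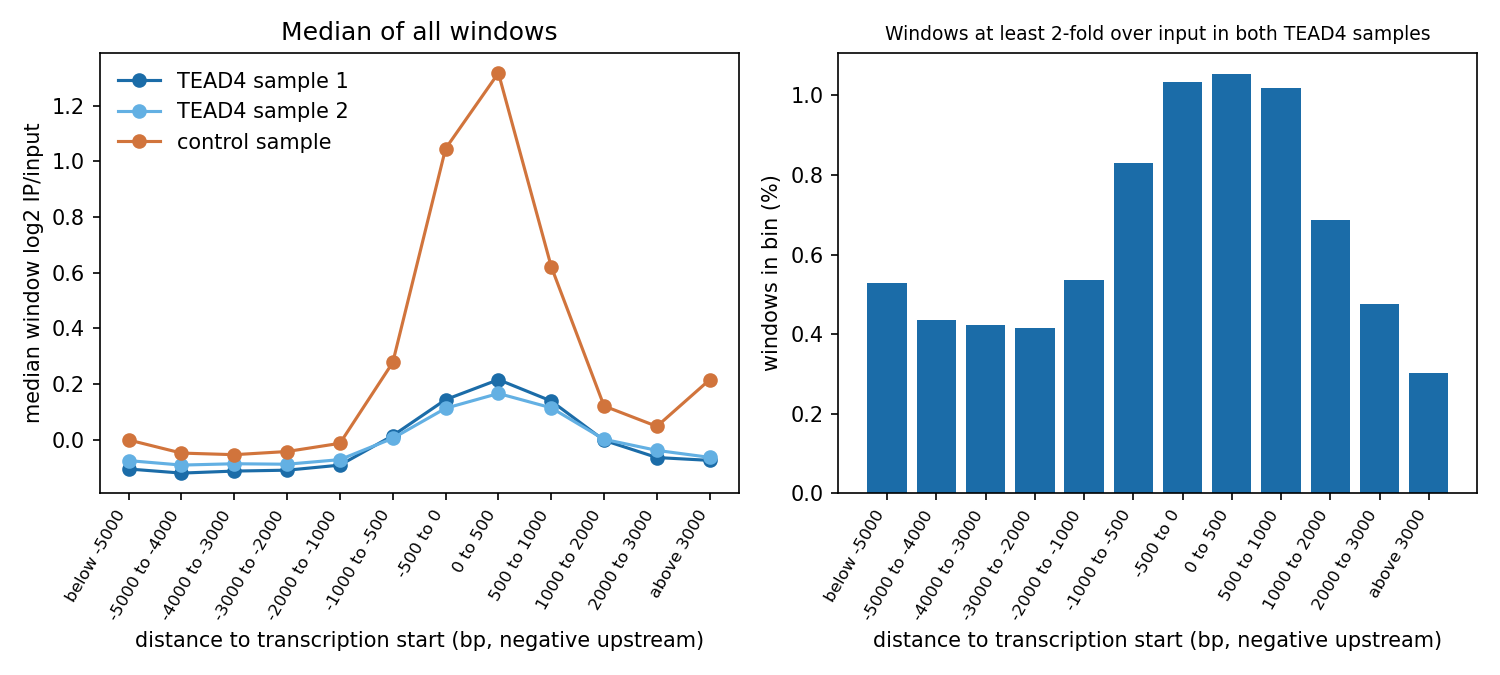
Left, median window log2 IP/input in each sample by distance to the transcription start (bp). Right, percent of windows in each distance bin at least 2-fold over input in both TEAD4 samples. The control median reaches 1.32 just downstream of the start against 0.22 and 0.17 in TEAD4, and the share of enriched windows reaches 1.05% in the same bin.

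The TEAD4 samples correlated more with each other than with the control. Across 428057 windows, log2 IP/input of the 2 TEAD4 samples gave a Pearson r of 0.57 and a Spearman rho of 0.51. Windows overlap and are not independent replicates, and a dye effect shared by the arrays could also raise these values. Against the control, r was 0.33 for sample 1 and 0.23 for sample 2, and rho was 0.36 and 0.26. The control's weak IP signal could lower these values, so they do not show how much pattern it shares. The differences of the 2 TEAD4 samples from the 1 control correlated at 0.94, where simulated unrelated samples with the same spreads and a shared control gave 0.88. Their covariance was 0.949, against 1.08 simulated. The simulation takes the TEAD4 samples as unrelated to the control, which they were not, so these values do not decide how much the TEAD4 samples share beyond the control. The 1 control sample could not be split.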

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

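The search outside annotated genes and its rule were chosen after the data were seen. The comparisons of genes leave out probes to which the array annotation gives no RefSeq gene. Among 11741 such windows, 43 were at least 2-fold above both input and control in both TEAD4 samples, against 12 under the mirrored rule, and they formed 16 regions. The share, 0.366%, stood beside 0.258% of windows with a gene, a difference that was not tested. A region on chromosome 1 from 23224578 to 23226437 had a top window with a log2 IP/input of 2.11 ± 0.02 (SD, n = 2) with -0.61 in the control. Another on chromosome 6 from 135316810 to 135318606 had 1.70 ± 0.02 (SD, n = 2) with -0.94 in the control. These regions were picked for small SDs after their values were seen, and what lies there was not analysed here.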

How the results depend on the processing

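Centring of windows, the dim IP filter, the mirrored rule, limma against 0 for genes over input, the probe-number variance, the lists over input, limma scaled by median absolute deviation, and 1.5-fold and 3-fold over input were chosen after the data were seen. The 859 genes over input kept within 1.5 times under loess, 300 bp, window medians, at least 4 probes and the dim probe filters, and the series matrix gave the same 859 genes. The count was 555 with normexp (495 shared), 368 with 1000 bp, 3333 at 1.5-fold, 128 at 3-fold, 1330 to 2568 without 1 TEAD4 sample, 422 if also over the control and 54 for the mirrored rule. Against the control, limma gave 328 higher and 802 lower with normexp, 3430 higher with loess, 1017 higher with single probes, 1181 and 1276 with quantiles, 4333 higher with centred windows, and 128 and 34 with scaled arrays. Without the control, against 0, it gave 3957 and 1948, and with the variance by number of probes 4262 and 1780. Genes 2-fold above and below the control were 1318 and 1788 with normexp and 2897 and 7458 with scaled arrays. Those above were 2174 with 1000 bp, 8539 with centred windows, 10475 at 1.5-fold, 785 at 3-fold, and 6996 to 7588 without 1 TEAD4 sample. Genes over input in the control were 3136 with normexp. The r of the TEAD4 samples was 0.456 with normexp, 0.628 with loess, 0.533 with 300 bp, 0.619 with 1000 bp, 0.525 with medians and 0.413 with single probes. Lists passing among genes above the control, 1 at first, were 3 with normexp, 0 with loess, 2 with either TEAD4 sample left out, 4 over input and 2 over input and control. The cause was not tested for these changes, except where fewer samples or another threshold sets the count.

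Of 249 alternatives for 29 named genes, 165 moved TEAD4 minus control by at most 1 SD, 73 by more, and 11 changed its sign. They concern the window with the largest TEAD4 minus control. For some genes, such as Acta1 (window at -3484 bp, TEAD4 mean -0.17), it is not the window over input printed above. These counts do not cover the values over input. Acta1 was at -0.0054 and Gapdh at 0.0094 with normexp, and Gapdh at 0.17 with loess. With 1000 bp Actb was at -0.59, Ccn2 at -0.48 and Ddit3 at -0.50. Ckm, at -0.02 before, was at 0.32 with normexp, 0.32 with loess, 0.18 with 300 bp, 0.47 with medians and 0.44 without TEAD4 sample 1. The cause was not tested.

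Leaving out a TEAD4 sample leaves limma no residual degrees of freedom, so no such test was run. The TEAD motif was not run, since no genome was used here. No paired analysis was possible because the control is 1 sample whose label carries no number. IP signal over background of 1.84 and 2.06 limits the control.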

Other observations

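The test of gene families was added after the data were seen but before its own result. The tests of scale, of distance as the whole cause and of active promoters were chosen after the results were seen. Among groups of 10 or more genes that share the letters of their symbol, Klf genes, zinc finger transcription factors, had 5 of 16 members enriched over input in both TEAD4 samples (Klf4, Klf5, Klf6, Klf7 and Klf13; Fisher's exact test, adjusted p = 0.109), which fails the correction. Eif genes, translation initiation factors, had 8 of 51 (Fisher's exact test, adjusted p = 0.324). In the 215 groups tested, 0 were higher at an adjusted p under 0.05 and 7 at an unadjusted one by Fisher's exact test, so a family beyond chance was not found, and 1, the olfactory receptors, was lower.

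More genes were lower than higher in TEAD4 against the control, and among the probes brightest in input the control's median absolute deviation was 4.40 times that of the TEAD4 samples, but its IP signal there was 4.19 and 5.88 times background against 10.1 and 12.6 in the same probes of TEAD4 sample 2. TEAD4 arrays of comparable IP signal over all probes (3.62 to 5.45) had deviations of 0.303 to 0.337 against 1.28 and 1.23 in those control probes, which argues against dim probes as the whole cause, although normexp left 802 limma calls lower. After scaling, genes lower outnumbered genes higher 2.57 times by the size rule, against scale alone. By limma the ratio was 0.266, but from only 128 genes higher and 34 lower. The scaling also raised the SD that limma pools over windows, from 0.239 to 0.405 on design 1 and from 0.216 to 0.389 on design 2. The lost calls may be lost power, so the limma ratio does not decide whether a wider scale accounts for the limma calls. Windows over 2000 bp from a start were still lower 4.21 times as often as higher, against distance as the whole cause, and distance explained 0.148 of the control's variance and 0.0698 of the TEAD4 samples', a share between the bounds set for it, so its part stays open. Batch, the control's separate extraction and a biological difference stay open.

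Windows enriched over input in TEAD4 could reflect background of the precipitation. In the top windows of the 859 genes the excess over distance-matched windows was 5.41 and 6.64 median absolute deviations in the TEAD4 samples. In the control it was 0.0943 (95% bootstrap interval -0.0153 to 0.217), a ratio of 0.0157. In log2 units the excess was 1.38 in TEAD4 and 0.0671 in the control, whose deviation is wider. The windows were chosen for high TEAD4 values, so the TEAD4 excess and the ratio were set by that choice. Only the control's excess is free of it, and it shows little rise at these windows in this 1 sample of weak IP signal. The interval does not cover spread between control samples. Their median input signal lay at the 48.9th percentile of windows, which argues against dim input. TEAD4 occupancy is a hypothesis that these tests leave in place. Background particular to the days of the TEAD4 samples stays open. All arrays had the same dye orientation, and a dye effect on values over input was not tested.

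The muscle and YAP-responsive lists may stand out because their promoters are active. At 2-fold their share was 2.47 times that of ribosomal and housekeeping genes (Fisher's exact test, p = 0.00337). With the window also 2-fold above the control, 18 of 118 passed against 4 of 107 (Fisher's exact test, p = 0.00351). The pooled lists, YAP-responsive, sarcomere and excitation-contraction, were those most enriched in these same data, so both p-values partly restate that choice. The demand over the control is also harder to meet where the control is high. Its median in the top windows was 1.34 for housekeeping and 0.746 for ribosomal genes, against 0.406, 0.436 and 0.776 for the pooled lists in that order. At 1.5-fold the ratio of shares was 0.937, so active promoters and list identity cannot be told apart by shares that differ with the threshold. The lists' medians exceeded 100% of random lists matched on the number of windows, against more windows per gene as the cause, but those of the ribosomal and housekeeping lists did so too.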
